A study of Zea mays with 4 samples.

How the data were processed

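Small RNA was sequenced from immature maize ears that were homozygous for the mop1-1 allele, which disables the RNA-dependent RNA polymerase RDR2 (MOP1). The labels give 4 libraries, all of this genotype and described as biological replicates, with ears of 3 to 5 cm. There was no wild-type or heterozygous group, so comparisons were made between classes of small RNA inside each library. The files do not measure the mRNA of the mop1 gene (LOC100502460 in the name table of the Zm-B73-REFERENCE-NAM-5.0 assembly), so the genotype could not be checked from them.

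Per the labels' protocols, adapters were removed from the Illumina reads and the abundance of each distinct sequence was counted. The deposited values are raw read counts, given for each distinct sequence with no normalization. Each file listed sequences of 18 to 31 nt. The trimming tool, quality filters, aligner and genome build are not given in the sources used here. The libraries held 15495793, 14212640, 14686514 and 15448835 reads for replicates 1 to 4. A single read was worth between 0.0645 and 0.0704 RPM (reads per 1e6 reads of the library), and a count of 0 allowed up to 0.194 to 0.211 RPM (3 counts of the total). Intervals and such limits cover counting error only, since reads without molecular identifiers are not independent molecules.

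Counts were converted to RPM of all reads in the library. Size ratios, the share of sequences that begin with A or U, and GC content were computed within each library for 21, 22 and 24 nt. They were then averaged over libraries and tested with an exact sign-flip permutation test (two-sided). With 4 libraries the smallest p this test can give is 0.125, and with 3 libraries it is 0.25, so no such comparison can reach 0.05. Base composition at positions 1 to 10 from each end, as the share of distinct sequences with each base, was tested with limma on paired differences of log2 odds over 80 features. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 with a difference of at least 1 percentage point.

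Families of known small RNAs were taken from lists fixed before the data were examined. They held 28 miRNA families, the tasiARF ta-siRNA, 4 tRNA 5' ends, 4 animal miRNAs and 5 miRNAs of eudicots. A read of 19 to 24 nt was assigned to a family when bases 3 to 18 of the listed mature sequence occurred in it, starting up to 5 bases from the 5' end of the read. The 22-nt and 21-nt forms of each family were compared with edgeR's quasi-likelihood test, with the library as a block and library totals as offset, for families with at least 10 reads in at least 4 of 8 columns. Family lists were compared with an exact permutation of list labels over families on the mean of log2(RPM + 0.1). The spread between libraries was measured as edgeR's common dispersion over sequences with at least 10 reads in at least 2 libraries, after TMM scaling.

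Full values were given for the 12 miRNA families highest in mean RPM, the anther triggers, tasiARF and the background lists, and for the 5 most abundant sequences of 21, 22 and 24 nt, of which 1 is not reported here. This rule, the main tests and the main alternatives to them were set before the data were examined. The limma test recovered 20 of 20 features shifted by 0.2 log2 odds in simulated data of 80 features for 24 against 21 nt. It made 1 false call among the unchanged features, without the rule of at least 1 percentage point. The edgeR test recovered 10 of 10 families changed by a log2 fold of 2 in simulated data of 29 families, with 2 false calls among the unchanged families. In the real data 24 families were tested. The simulated noise was preset (a dispersion of 0.16 for edgeR) and not estimated from these libraries, so these recoveries do not measure power in these data.

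Alternatives to each choice (reads or distinct sequences, count filters, abundant sequences left out, other scaling, DESeq2, other matching of reads to families, each replicate left out) were computed. Because substitutions at read position 12 were found, values with that position masked were added after the data were seen. A reference genome was not used here, so genome matches, genic shares and phased loci were not analysed here. Python 3.11.15, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.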

Results

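Small RNAs of 18 to 31 nt were profiled in 4 libraries from immature ears of homozygous mop1-1 maize. RDR2 (MOP1) makes the double-stranded RNA from which most 24-nt siRNAs are cut in wild-type plants. The series concerns how reproductive phasiRNAs can be told from other small RNAs of the same size. Totals ranged from 14212640 to 15495793 reads. Distinct sequences numbered 2088731, 2924544, 2639106 and 2656023 in replicates 1 to 4, and 49.5%, 76.1%, 75.7% and 75.9% of them were read once.

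Replicate 1 stood apart from replicates 2 to 4 in miRNA content, base composition and shared sequences. miRNAs of the listed families made up 1.54% of reads in replicate 1 and 9.77%, 9.95% and 8.34% in replicates 2 to 4. These shares leave out reads substituted at read position 12, which were frequent only in replicates 2 to 4. GC content of distinct sequences was 57.9% in replicate 1 and 49.6%, 49.9% and 50.1% in the others. Sequences also found in another library held 55.0% of the reads of replicate 1 and 85.4%, 87.8% and 87.9% of the reads of replicates 2 to 4. Replicate 1 shared 8.09%, 7.55% and 7.45% of its distinct sequences with replicates 2, 3 and 4. Among replicates 2 to 4 the shared part was 29.02%, 27.8% and 26.9% of the smaller set. Over 112501 sequences with at least 10 reads in at least 2 libraries, Pearson's r of log2 RPM was 0.11, 0.09 and 0.12 for pairs with replicate 1 and 0.88, 0.83 and 0.86 for the other pairs. These are correlations across sequences, which are not independent replicates. On replicates 2 to 4 alone 108849 sequences pass the same filter, so the set favours agreement among those libraries. It also holds sequences substituted at read position 12, which was not masked here. The biological coefficient of variation from edgeR's common dispersion was 1.03 over the 4 libraries and 0.395 without replicate 1. No label sets replicate 1 apart, so it was kept in each mean.

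**Figure D1:**
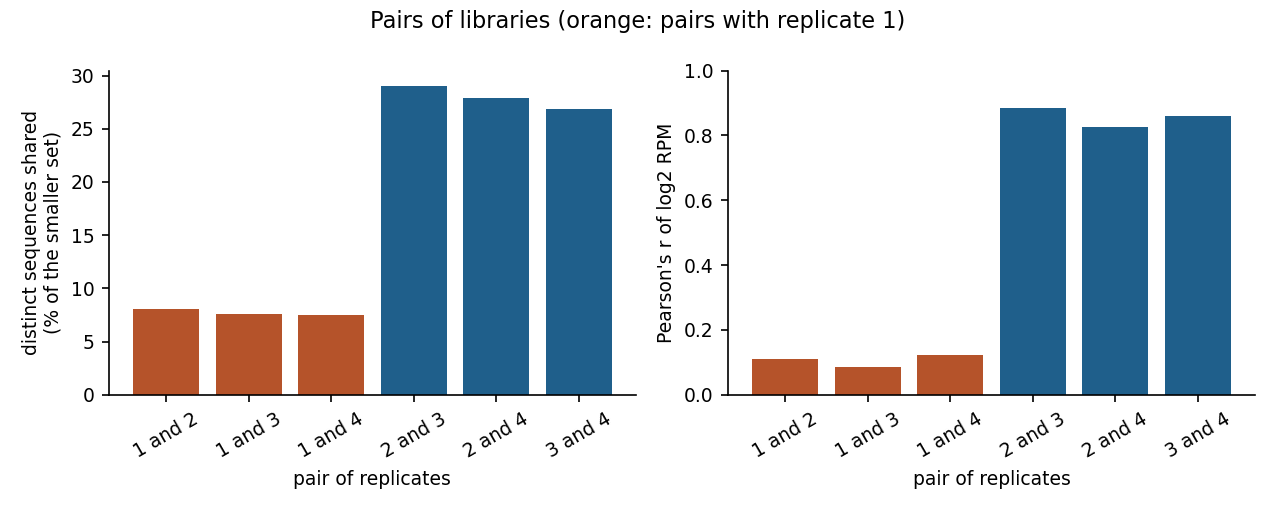
Distinct sequences shared by each pair of libraries, as a percent of the smaller set (left), and Pearson's r of log2 RPM over 112501 sequences (right). Orange bars are pairs with replicate 1, at 7.45% to 8.09% shared, and blue bars are the other pairs, at 26.9% to 29.02%.

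The size comparison addressed which read lengths dominate in these mop1-1 ears. Fragments of rRNA and tRNA were not removed, so a length class is not a count of siRNAs or miRNAs. The 22-nt class held the most reads in each of the 4 libraries, with 29.2% ± 8.41 of reads (SD, n = 4), against 16.0% ± 4.58 for 21 nt and 16.2% ± 1.74 for 24 nt. In single libraries the 22-nt share was 40.8%, 29.8%, 24.7% and 21.6% for replicates 1 to 4. The 24-nt reads were fewer than the 22-nt reads by a log2 ratio of -0.82 ± 0.26 (SD, n = 4), with the same direction in 4 of 4 libraries and p = 0.125 in the exact sign-flip permutation test, the smallest value it can give. Over replicates 2 to 4 that ratio was -0.71 ± 0.15. Counted once per sequence, the order turned, with 24-nt above 22-nt sequences by 0.12 ± 0.11 in log2 (4 of 4 libraries). The 22-nt reads exceeded 21-nt reads by 0.88 ± 0.84 in log2 in 4 of 4 libraries (exact sign-flip permutation p = 0.125), and by 0.47 ± 0.13 over replicates 2 to 4. The 24-nt and 21-nt reads did not differ in a common direction, with a log2 ratio of 0.06 ± 0.61 (exact sign-flip permutation p = 1). That ratio was 0.97 in replicate 1 and -0.22, -0.32 and -0.18 in replicates 2 to 4. Without the reads of the listed families, 24-nt reads exceeded 21-nt reads by 0.73 ± 0.33 in log2 in 4 of 4 libraries.

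**Figure D2:**
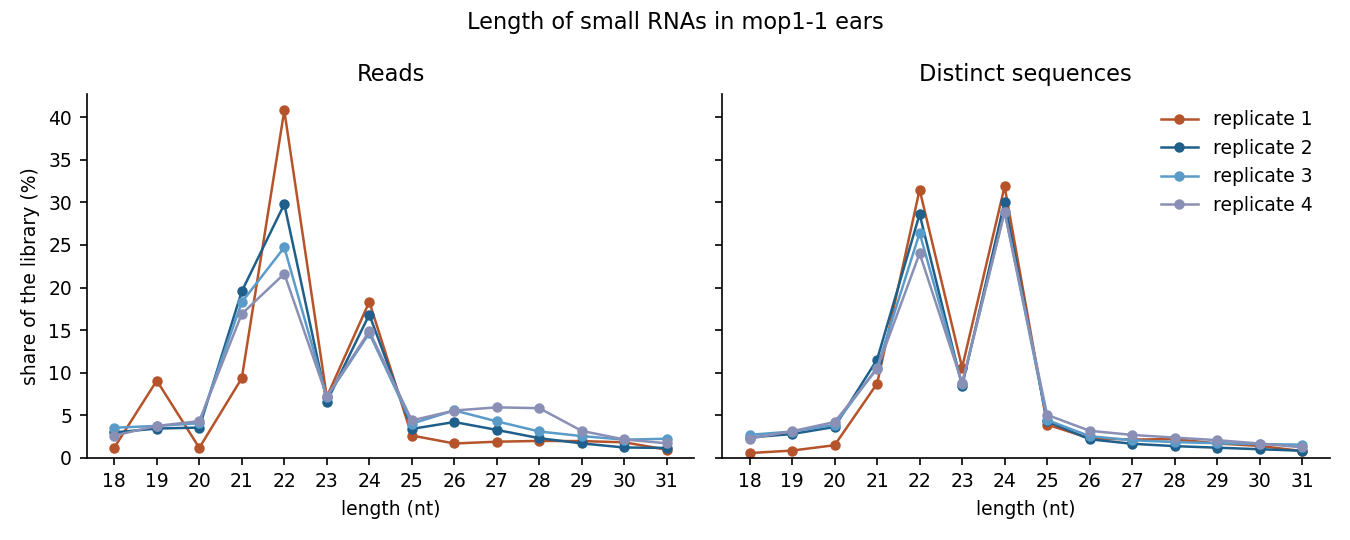
Share of reads (left) and of distinct sequences (right) of each length from 18 to 31 nt in percent of the library, with a line for each replicate. Reads peak at 22 nt in each library, at 21.6% to 40.8%, while distinct sequences of 22 and 24 nt are close to each other.

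The base at the 5' end, which follows the Argonaute protein that holds a small RNA, separated 24-nt from 21-nt and 22-nt sequences. Of distinct 24-nt sequences 40.3% ± 6.49 began with A and 18.03% ± 0.606 with U (SD, n = 4). For 21-nt sequences the shares were 26.6% ± 2.43 with A and 30.2% ± 4.32 with U, and for 22-nt sequences 26.9% ± 2.80 and 31.7% ± 3.70. The A share was higher in 24-nt than in 21-nt sequences by 13.6 ± 4.07 percentage points, and the U share was higher in 21-nt than in 24-nt sequences by 12.2 ± 4.77 points. Each had this direction in 4 of 4 libraries, with p = 0.125 in the exact sign-flip permutation test. Over replicates 2 to 4 the differences were 15.6 ± 0.386 and 14.5 ± 0.242 points, and in replicate 1 they were 7.51 and 5.01 points. Weighted by reads, the A difference was 21.7 ± 9.30 points and the U difference 32.3 ± 17.6 points (7.89 and 6.18 points in replicate 1). A single miR166 form, which begins with U, held 25.1%, 33.8% and 30.5% of the 21-nt reads in replicates 2 to 4. Differences weighted by reads, also that of GC content, therefore depend in part on this form and were not recomputed without it. GC content differed by -0.963 ± 0.197 points between 24-nt and 21-nt sequences (lower at 24 nt in 4 of 4 libraries, exact sign-flip permutation p = 0.125). It differed by -6.29 ± 3.63 points weighted by reads (-0.854 in replicate 1) and by -2.11 ± 0.950 points over sequences with at least 2 reads. With read position 12 masked the GC difference shrank to -0.711 ± 0.0970 points. In replicates 2 to 4 it went from -1.03, -0.953 and -1.17 points to -0.702, -0.605 and -0.841 points. In replicate 1 it was -0.698 points unmasked and -0.697 masked.

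**Figure D3:**
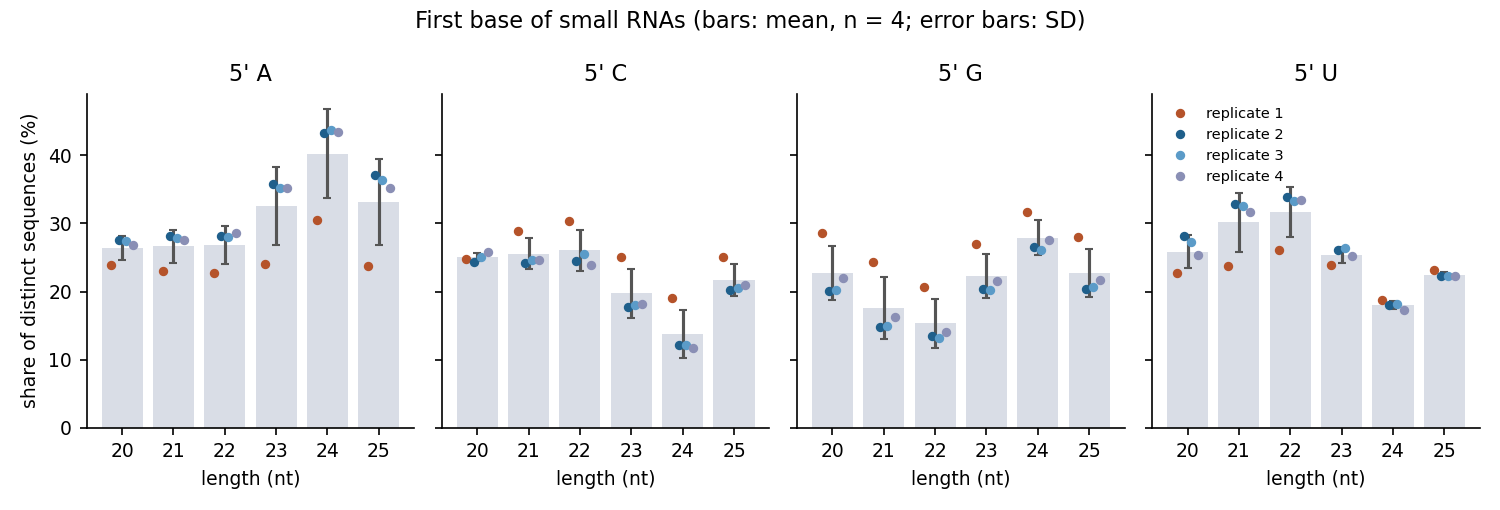
Share of distinct sequences of 20 to 25 nt that begin with each base, in percent. Grey bars are means over 4 libraries with SD, points are libraries, and at 24 nt A reaches 40.3% on average against 26.6% at 21 nt.

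Position by position, limma called 37 of 80 base shares as different between 24-nt and 21-nt sequences, 19 higher and 18 lower at 24 nt. At the first position of the 5' end, C was lower at 24 nt by -11.8 points (13.8% against 25.6%, limma adjusted p = 0.00138) and G was higher by 10.3 points (27.9% against 17.6%, limma adjusted p = 0.00276). At the third position from the 3' end, A was higher at 24 nt by 10.95 points (29.3% against 18.3%, limma adjusted p = 9.5e-05) and U was lower by -5.15 points (12.4% against 17.5%, limma adjusted p = 9.5e-05). Against 22-nt sequences 29 features were called, 16 higher and 13 lower at 24 nt, with A at the third position from the 3' end again higher, by 8.27 points (limma adjusted p = 0.000692). The 22-nt and 21-nt sequences differed in 27 features, 11 higher and 16 lower at 22 nt. At the 5' end, G was lower by -2.23 points (limma adjusted p = 0.000532) and U was higher by 1.52 points (limma adjusted p = 0.00921). Read position 12, where replicates 2 to 4 carried substitutions, is position 10 from the 3' end of a 21-nt sequence. At position 10 from the 3' end, G was called lower at 24 than at 21 nt by -3.44 points (-4.49 over replicates 2 to 4, -0.274 in replicate 1). G was also called lower at 22 than at 21 nt, by -3.42 points (-4.36 and -0.595). C was called higher in both comparisons, with 1.85 and 1.39 points in replicate 1, and U in the second. The counts of 37 and 27 include these calls. The limma fit over 80 features was not rerun with that position masked, so their dependence on the substitutions was not tested. Without replicate 1 the counts were 45, 39 and 33; without replicate 3 the first was 24, and without replicates 2, 3 and 4 the second was 15, 14 and 12.

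miR166, which restrains class III HD-ZIP genes in organ polarity, had the highest mean of the 28 listed miRNA families. It reached 45230 ± 30325 RPM (SD, n = 4), with 443 RPM in replicate 1 and 60160 ± 6493 RPM over replicates 2 to 4. With any base allowed at read position 12, where replicates 2 to 4 carried substitutions, the miR166 mean was 51971 RPM. miR319, which targets TCP transcription factors, followed at 18501 ± 13275 RPM, with 343 RPM in replicate 1 and 24554 ± 6675 RPM in the others. miR529, which targets SPL genes in grasses, was at 3255 ± 2588 RPM over the 4 libraries, at 0.774 RPM in replicate 1 and at 4339 ± 1729 RPM in the others. miR172, which targets AP2-like floral genes, had 2023 ± 4030 RPM, of which replicate 1 gave 8068 RPM while the others averaged 7.78 ± 3.29 RPM. miR168, which targets AGO1, had 957 ± 644 RPM, with 47.3 RPM in replicate 1 and 1261 ± 264 RPM in the others. miR159, which targets GAMYB genes, had 892 ± 409 RPM, with 341 RPM in replicate 1 and 1076 ± 219 RPM in the others. miR156, which targets SPL genes, had 2404 RPM in replicate 1 and 108 ± 50.0 RPM in the others. miR394 had 355 ± 489 RPM, of which replicate 1 gave 1087 RPM while the others averaged 111 ± 33.9 RPM. In miR396, at 330 ± 76.0 RPM, replicate 1 had 429 RPM and the others 297 ± 46.9 RPM. miR827 had 286 ± 188 RPM, with 6.65 RPM in replicate 1 and 380 ± 25.5 RPM in the others. For miR408, at 273 ± 217 RPM, the values were 1.87 RPM and 363 ± 147 RPM. The miR169 mean of 270 ± 511 RPM came from replicate 1, at 1036 RPM, since the others averaged 14.6 ± 3.06 RPM. This ranking follows the main matching, which put miR397 at 5.33 RPM. By a shorter inner core of the listed sequence miR397 had a mean of 2294 RPM, above that of miR172. The ta-siRNA tasiARF, made from TAS3, had 2721 RPM in replicate 1 and 58.7 ± 18.4 RPM over replicates 2 to 4. Of the 16 development families, 9 were higher in replicate 1 than in each other library and 7 were lower. Of the 8 nutrient and stress families, 1 was higher and 6 were lower.

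Anther triggers of reproductive phasiRNAs were rare in these ears. miR2118, which triggers 21-nt phasiRNAs, had 97 reads in all (0, 26, 62 and 9 in replicates 1 to 4), and 0 reads in replicate 1 allows up to 0.194 RPM. miR2275, which triggers 24-nt phasiRNAs, had 23 reads in all, with 9, 8, 1 and 5 per library. miR162 and miR168, which target DCL1 and AGO1, summed to 1103 ± 746 RPM (1452 ± 319 RPM over replicates 2 to 4) and were both lower in replicate 1. The 4 listed tRNA 5' ends summed to 456 ± 98.0 RPM, with 407 RPM in replicate 1 and 473 ± 113 RPM over replicates 2 to 4. This sum is not a total for tRNA fragments. It leaves out a tRNA-like sequence of 19 nt that took 8.21% of the reads of replicate 1. The 4 animal miRNAs had 0 reads in each library. The 5 eudicot miRNAs had 455 reads (29.4 RPM) in replicate 1 and 1, 1 and 0 in replicates 2 to 4.

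**Figure D4:**
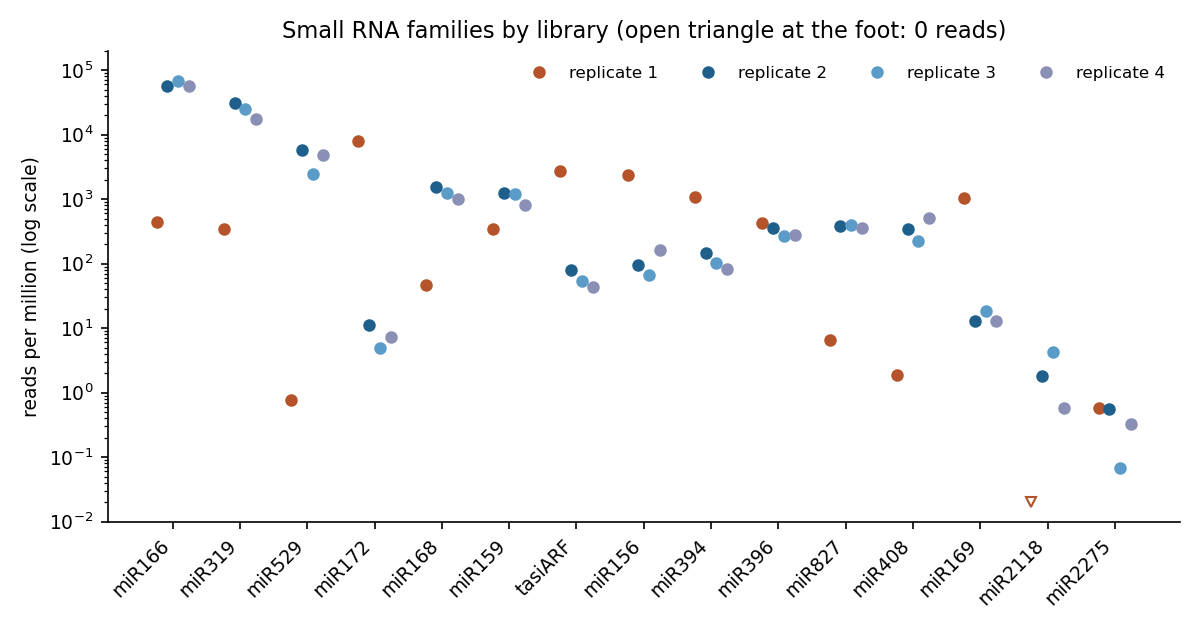
RPM, on a log scale, of the 12 most abundant miRNA families by the main matching, tasiARF and the 2 anther triggers, with a point for each library. miR397, at a mean of 5.33 RPM by that matching and 2294 RPM by a shorter inner core, is not shown. miR172, tasiARF, miR156, miR394 and miR169 are highest in replicate 1, and miR166 ranges from 443 to 67631 RPM.

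Development families had a higher median than nutrient and stress families over the 4 libraries, and the call rested on replicate 1. The medians of mean log2(RPM + 0.1) differed by 3.58, an 11.96-fold difference, over 16 and 8 families (p = 0.00413, exact permutation of list labels over families, two-sided). Without replicate 1 the difference was 2.01 with p = 0.220 in the same exact permutation test. Replicate 1 alone gave a 225-fold difference (exact permutation p = 0.0137), and replicates 2, 3 and 4 alone gave 3.80-fold, 5.22-fold and 2.76-fold (exact permutation p = 0.297, 0.121 and 0.431). Matching families by a shorter inner core of the listed sequence also ended the call (difference 2.07, exact permutation p = 0.0698) and moved the nutrient family miR397 from 5.33 to 2294 RPM. The main difference therefore leaves out nearly all miR397 reads found by the inner core. Families are not replicate samples, so the test compares lists in this tissue.

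The 21-nt form exceeded the 22-nt form in 23 of the 24 families tested with edgeR, and 0 families were called with a higher 22-nt form. The read filter left 5 listed families untested. Among them were miR2118 and miR2275, with on average 96.4% and 96.9% of their few reads at 22 nt. The lack of a higher 22-nt form thus holds for the tested families only. In replicate 1 the 22-nt form was the more abundant for miR159 (1186 reads of 21 nt and 1509 of 22 nt) and for miR393 (4 and 7 reads). The call for miR159 ended without replicate 2 or 3 (edgeR adjusted p = 0.0639 and 0.0801), though its log2 fold was still -2.21 and -2.19, against -2.53. That for miR393 ended without replicate 2, 3 or 4 (edgeR adjusted p = 0.125, 0.172 and 0.103). That for miR394 ended in the same omissions (edgeR adjusted p = 0.116, 0.168 and 0.0648). That for miR169 ended without replicate 2 (edgeR adjusted p = 0.0639), with a log2 fold of -2.08 against -2.02. In miR394 the test compared minor forms, since on average 92.8% of its reads were 20 nt, 1.55% 21 nt and 0.362% 22 nt. For miR156 the 20-nt share averaged 55.2%. In miR529 the 22-nt form was 0.0279% ± 0.0196 of both forms (log2 fold -11.38, edgeR adjusted p = 7.31e-06). In miR166 it was 0.502% ± 0.647 (log2 fold -8.47, edgeR adjusted p = 0.000134), with 1.47% in replicate 1 and 0.203%, 0.170% and 0.161% in replicates 2 to 4. Without replicate 1 the miR166 log2 fold was -9.14. In miR168 the share was 6.71% ± 2.11 (log2 fold -3.84, edgeR adjusted p = 6.05e-05). The miR319 forms did not pass the test, with 43.3% ± 7.58 of reads in the 22-nt form (log2 fold -0.39, edgeR adjusted p = 0.271). Counting only reads that start at the listed first base, which leaves out CTTGGACTGAAGGGTGCTCCCT, the miR319 log2 fold was -3.18 (edgeR adjusted p = 0.000128). Scaling by TMM or by DESeq2's size factors takes out most of the difference common to all families, a median shift of 3.86 or 4.75 in log2. On those scales 4 and 6 families were called with the 22-nt form higher, among them miR319, miR167, miR393 and miR394.

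By mean, the most abundant 21-nt sequence was the miR166 form TCGGACCAGGCTTCATTCCCC at 40644 ± 27466 RPM (SD, n = 4), followed by the miR319 form TTGGACTGAAGGGTGCTCCCT at 8511 ± 6193 RPM. This order does not hold in replicate 1, where they had 272 and 202 RPM (4218 and 3126 reads) and another sequence led with 6.22% of 1448731 reads of 21 nt. AGAAGAGAGAGAGTACAGCCT of miR529 had 3128 ± 2481 RPM and TTGAGCGCAGCGTTGATGAGC had 2271 ± 1806 RPM. The latter holds the shorter inner core of miR397 and is missed by the main matching. By the inner core miR397 had 29.2, 2800, 1969 and 4378 RPM in replicates 1 to 4 (mean 2294 RPM), against a mean of 5.33 RPM by the main matching. At 22 nt the highest mean was that of CTTGGACTGAAGGGTGCTCCCT of miR319, at 6796 ± 4864 RPM, with 75.5 RPM in replicate 1. There AAGCTAGCTATTTTGCCGAGCA led, with 16663 RPM, against 0.499 ± 0.124 RPM in the others. GCCCCGCGTCGCACGGATTCGT had 3921 ± 2876 RPM, GCCGGCGATGCGCTCCTGGCCT 2362 ± 1397 RPM and CGACACGACTCTCGGCAACGGA 1764 ± 1220 RPM. At 24 nt the order by mean was CAGCCCCGCGTCGCACGGATTCGT at 2005 ± 1438 RPM, TTTGCACCGTTGGTCTGAAAGATA at 1618 ± 1120 RPM and GTGTACTCTAATGAGCTGGACGCA at 889 ± 1777 RPM. The last of these had 3554 RPM in replicate 1 and 0.699 ± 0.0161 RPM in the others. ACACGACTCTCGGCAACGGATATC had 763 ± 526 RPM and CGACACGACTCTCGGCAACGGATA had 737 ± 461 RPM. Each of these 24-nt sequences except GTGTACTCTAATGAGCTGGACGCA was higher in replicates 2 to 4 than in replicate 1.

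Abundant small RNAs such as miR166 and miR319 carried substitutions at read position 12 in replicates 2 to 4. Over the 200 most abundant sequences of each library the median substitution rate at that position was 12.6%, 12.5% and 12.6% in replicates 2 to 4 and 0.0792% in replicate 1. At no other position did a median exceed 0.241%. These substitutions raise the number of distinct sequences: with position 12 masked, replicates 2 to 4 held 2530467, 2274769 and 2299369. They also keep reads out of the main family matching, which lowers family RPM in replicates 2 to 4. With any base allowed at position 12, mean RPM was 20157 for miR319 (18501 in the main matching). For miR529 it was 3720 (3255 in the main matching).

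**Figure D5:**
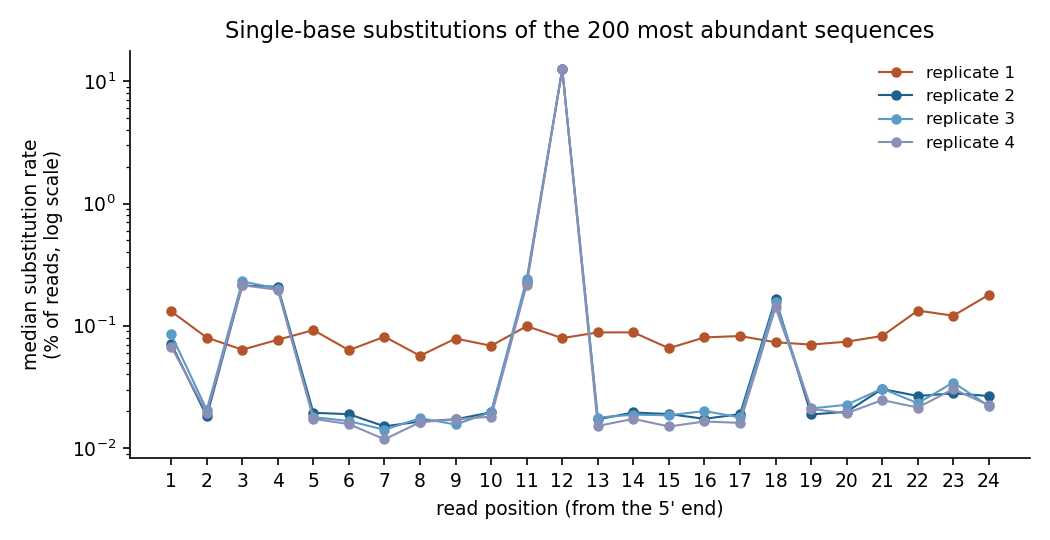
Median rate of single-base substitutions by read position over the 200 most abundant sequences of each library, in percent of reads on a log scale. Replicates 2 to 4 peak at position 12 at 12.5% to 12.6%, and replicate 1 stays near 0.0792% there.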

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

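Tests of replicate 1 and of the substitutions were chosen after the patterns had been seen but before their own values were computed. Over 55 values with 4 libraries each, a library was set apart by the gap to its nearest neighbour in 17, and it was replicate 1 in 17 of 17. Chance sets apart about 1 in 20 single groups. That rate does not apply to the tally, because the 55 values come from the same libraries, overlap with each other and were in part chosen after replicate 1 had been seen to differ.

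Replicate 1 had far more of some families than the others: 8068 RPM of miR172, 2721 RPM of tasiARF, 2404 RPM of miR156, 1087 RPM of miR394 and 1036 RPM of miR169. It had less of others: 0.774 RPM of miR529, 1.87 RPM of miR408, 443 RPM of miR166, 343 RPM of miR319 and 6.65 RPM of miR827. Of these only miR827 was set apart by the gap. The eudicot miRNAs summed to 29.4 RPM there. AAGCTAGCTATTTTGCCGAGCA had 16663 RPM and GTGTACTCTAATGAGCTGGACGCA had 3554 RPM, nearly all of their reads. GC content was 57.9%, the share of distinct sequences read once 49.5% and the share of reads in sequences also found elsewhere 55.0%. The log2 ratio of 24-nt to 21-nt reads was 0.97 and that of 22-nt to 21-nt reads 2.13. The A difference between 24 and 21 nt was 7.51 points and the U difference 5.01 points. Substitutions at position 12 had a median of 0.0792%. Reads outside 21, 22 and 24 nt, which no comparison of size classes used, averaged 38.6% of the libraries.

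Replicate 1 shared few sequences with replicates 2 to 4. Read errors at position 12 are argued against as the cause, since masking that position left the mean share at 8.07%, against at least 26.9% among replicates 2 to 4. GC content bias is argued against too: within strata of the same length and GC, the median rank correlation of replicate 1 with the others was 0.1003, against 0.764 among replicates 2 to 4. Without strata the rank correlations with replicate 1 were 0.0785, 0.0585 and 0.0923. These sequences passed the read filter mostly through replicates 2 to 4, which favours the value among those libraries. The first and last base of a small RNA explained little of its ratio between replicate 1 and the others (adjusted R squared 0.0623, against 0.716 for the family over 194 forms). A different tissue, genotype, library batch, label or admixed plant could also give such a library, and none of these was tested; no biological explanation was tested.

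Substitutions at read position 12 in replicates 2 to 4 may be errors of a single sequencing cycle. In 3296 comparisons of forms of the same small RNA shifted by 1 base, the same RNA base was substituted at a median 108 times the rate when it fell at position 12. When it fell at position 11 or 13 the median rate was 0.0907%, which argues against a change in the RNA itself such as an allele or an edit. Each pair of forms entered once for each form's base at position 12, and replicates 2 to 4 were counted separately. The comparisons are therefore not independent, and the pairs are fewer.

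Distinct 22-nt sequences had a complementary partner of the same length with 2-nt overhangs in 9.58% ± 0.373 of cases, 24-nt sequences in 3.02% ± 1.01 and 21-nt sequences in 7.31% ± 1.03 (SD, n = 4). Unequal numbers of distinct sequences run against the gap between 22 and 24 nt, so drawing equal numbers was no test of its cause. The 24-nt class held more distinct sequences than the 22-nt class in each library (665655 against 657689 in replicate 1), which would favour partners at 24 nt. With 150000 sequences drawn per class, the ratio of the 22-nt to the 24-nt share was at least 1.98 in each library. The draw did not equalize reads per distinct sequence. In replicates 1 to 4 these were 9.61, 5.06, 5.21 and 5.24 at 22 nt and 4.26, 2.72, 2.82 and 3.00 at 24 nt. An effect of this depth on the gap was not tested. The drawn share of 21-nt sequences was 4.50% ± 1.83, above the 2.22% ± 0.241 of 22-nt sequences, so the order of 21 and 22 nt depends on the drawing. Precursors cut from long double-stranded RNA could give such pairs, a hypothesis not tested against a genome.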

How the results depend on the processing

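The alternatives with position 12 masked or free, and the shorter inner core, were chosen after the data were seen. Of 48 alternatives for the sign-flip comparisons 44 kept direction, and none could change side of the threshold by design. Of 9 for the family lists 7 kept direction and call, and of 42 for counts of calls and the coefficient of variation, 32 stayed within 1.5 times the main value. Counting distinct sequences turned the log2 ratio of 24-nt to 22-nt reads to 0.12, and to 0.23 with position 12 masked as well. The ratio of 24-nt to 21-nt reads turned to -0.55 with sequences of at least 10 reads and to -0.24 without replicate 1. The cause was not tested for these. Development against nutrient families fell to 2.07 (exact permutation p = 0.0698) with the shorter inner core, which also takes in a shifted miR397 sequence. Counts of features between 24 and 21 nt were 56 weighted by reads and 17 at 2 points. For 24 against 22 nt the count was 14 at 2 points. For 22 against 21 nt it was 60 weighted by reads and 6 at 2 points. Leaving out a replicate each time gave ranges of -0.91 to -0.71 (24 to 22 nt), -0.24 to 0.19 (24 to 21 nt) and 0.47 to 1.06 (22 to 21 nt). The ranges were 12.8 to 15.6 points for A, 11.3 to 14.5 for U, -1.05 to -0.894 for GC and 2.01 to 4.08 for development families. Feature counts ranged from 24 to 45, 12 to 39 and 23 to 33, family calls from 16 to 18, and the coefficient of variation from 0.395 to 1.28. Fewer families passed the read filter with a replicate left out. The calls were 18 of 19, 16 of 21, 17 of 21 and 18 of 21 tested families without replicates 1, 2, 3 and 4. Without replicate 1 the list difference was 2.01 (exact permutation p = 0.220) and the coefficient 0.395. Feature counts fell to 24 without replicate 3 (24 against 21 nt), and to 15, 14 and 12 without replicates 2, 3 and 4 (24 against 22 nt).

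Without the replicate block, edgeR called 19 families, against 23. With TMM, 17 were called, and the 22-nt form of miR159 (1.34), miR167 (2.24), miR169 (2.12), miR319 (3.45), miR393 (1.57) and miR394 (1.26) turned to the higher side. With DESeq2's own size factors, 16 were called and the same families turned, at 2.27, 3.16, 2.99, 4.35, 2.47 and 2.24, as did miR168 (0.89), miR390 (0.25), miR408 (0.83) and tasiARF (0.0247). These scales centre the common difference, which is their construction. Of 248 alternatives for single families, 207 kept their call. Splits that swap the lengths within libraries number 8, too few for a share under 0.05: only the real split (1 of 8) gave as many calls. Real and highest other counts were 37 and 0 (24 against 21 nt), 29 and 6 (24 against 22 nt), 27 and 0 (22 against 21 nt) and 23 and 0 (families). Genome-based results (genome matches, phased loci, genic share) and the genome-matched alternatives of the size, 5' base and GC results were not run. At these depths a family with 0 reads in a library could still be present there at up to about 0.211 RPM.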

Other observations

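All sequences in this part were chosen after their values were seen. A series of sequences of 18 to 29 nt that share the 3' end of GCCCCGCGTCGCACGGATTCGT held 2.84%, 5.17% and 3.95% of reads in replicates 2 to 4 and 0.108% in replicate 1. Its most abundant length was 27 nt in replicates 2 to 4 and 29 nt in replicate 1. Sequences that begin like plant 5.8S rRNA held 1.49%, 2.08% and 1.51% of reads in replicates 2 to 4 and 0.0712% in replicate 1. The tRNA-like sequence GGGCCTGTAGCTCAGAGGA of 19 nt took 8.21% of the reads of replicate 1. The sequence AAACCCGGGCGAAACGCTGCTGAAAC of 26 nt had 15423, 19273 and 12147 RPM in replicates 2 to 4 and 79.0 RPM in replicate 1.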
